A study of Homo sapiens with 20 samples.

How the data were processed

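Full-length cDNA was made from 0.5 ng of total RNA per sample by Smart-seq2, a protocol that amplifies polyadenylated RNA from few cells, and sequencing libraries were made with Nextera XT, per the labels. Reads of 50 bp were taken, single-end on a HiSeq2500 or paired-end on a NovaSeq6000, per the labels; which instrument read which library is not given in the sources used here, so a sequencer batch was not examined. The deposited counts are whole numbers per gene symbol and library, with TopHat2 2.0.9, HTSeq and the hg19 build named, without role or order, per the submitters' processing notes. The gene annotation, the strand setting and the treatment of reads shared between genes are not given in the sources used here. The deposited TPM, abundances scaled by gene length and library total, cover the same genes; how the authors computed TPM is not given in the sources used here. TPM divided by count, relative to a reference gene, was constant across libraries to a relative SD of at most 3.53e-06 over 2298 genes with more than 100 counts in every library, and no gene was at 0 in 1 table only, so the TPM hold no information beyond the counts and fixed gene lengths. The protocol does not mark strand, so reads of a gene and of an antisense partner cannot be told apart.

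Both tables held 26364 gene symbols and 20 libraries, and each column name equalled the title of its sample; 25255 symbols matched the RefSeq gene table by symbol or synonym. Its assembly is not the hg19 build, so no coordinates are given. There were 0 mitochondrially encoded genes in the tables, and the planned share of mitochondrial counts was not computed. Immunoglobulin and T cell receptor constant genes were not measured either, which leaves the plasma cell list with 7 of its 14 genes. Sex-linked genes of chromosome Y and the X-inactivation transcripts (14 of the genes tested) stayed in the fits, the list tests, the library quality measures and the counts of genes called. They were left out of the genes named, the correlations between libraries, the principal components and the count of genes moving the same way in all donors.

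The Tfr and Treg libraries share donors, per the labels, so the libraries are paired, and the donors are the replicates. Over 10983 genes, the deviations of a donor's libraries from their group means correlated with a mean r of 0.0663 (0.0106 to 0.251, above 0.1 in 2 of 10 donors) against -0.00700 between different donors, and 6 of 10 Tfr libraries correlated best with the Treg library of their own donor. Within a group, Spearman correlations between libraries ran from 0.562 to 0.783 in Tfr and from 0.491 to 0.726 in Treg over genes. The first principal component held 11.4% of the variance.

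Genes were tested on the counts with edgeR 4.0.16 in R 4.3.3 (filterByExpr with the group, TMM normalization, robust estimateDisp, glmQLFit and a two-sided glmQLFTest; contrast Tfr minus Treg, no donor block, Benjamini-Hochberg adjusted p at most 0.05). The filter left 10997 genes. The common dispersion was 1.23, a biological coefficient of variation of 1.11. Levels are TMM-scaled CPM, as mean ± SD over 10 libraries, and the SE of a log2 fold change is that implied by its F statistic. The median log2 fold change of all tested genes was -0.11 with TMM and 0.01 with upper-quartile normalization, and small fold changes are read against that shift. Gene lists were tested with camera in limma on voom values, two-sided, with a preset inter-gene correlation of 0.01 and with an estimated one, and adjusted over the 23 lists with at least 5 tested genes; the other 4 of the 27 lists are given as values. Members past the threshold were counted over all genes and adjusted over the list alone. Library quality was tested by two-sided permutation with 100000 resamples, and by exact sign flips within donors.

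The tests, the lists and the rule for named genes were fixed before the data were examined. The rule took the 12 genes of highest and the 12 of lowest log2 fold change among those with an adjusted p of at most 0.05, an absolute log2 fold change of at least 1, a mean of at least 10 CPM and the same direction in at least 8 of 10 donors, leaving out the sort markers, sex-linked genes, antigen receptor segments and identifiers without a symbol. It also took up to 4 members of each list past the threshold or, where none passed, up to 2 with the smallest p, given as values. No gene qualified under its first part, so genes are named from the lists; others were chosen after their values were seen, as said beside them. The alternatives were the donor as a block, DESeq2 1.42.0, limma 3.58.1 with voom sample weights, RLE and upper-quartile normalization, no filter or a filter of 5 CPM in 10 libraries, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), and leaving out each donor. After the data were examined, a filter at a mean of 50 CPM, voom without sample weights, the share of undetected genes as a covariate, the omission of the library with the fewest genes at 1 CPM or of the Tfr library with no CXCR5 count, and DESeq2 on thinned counts or on genes counted in at least 15 libraries were added. The summed CPM of class II genes and of myeloid and B cell markers was tested then too, by permutation and by exact sign flips within donors.

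The procedures were tested on simulated negative binomial counts for the 10997 genes with the means, dispersions and library sizes of the real libraries and 200 genes changed 2, 4, 8 or 16-fold. In that simulated comparison of Tfr against Treg, edgeR called 1, 10, 24 and 33 of 50 genes at these folds with 0 false calls, and DESeq2 called 2, 24, 38 and 45 with 46 false calls. Camera called 0 of 23 lists with no change and 21 of 23 when a list was shifted 2-fold, or 18 with an estimated correlation. Each gene was drawn independently, so the simulation cannot show how the preset correlation fares when list members vary together. In the real libraries the estimated correlation was 0.434 for HLA class II and 0.111 for follicular T cell genes.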

Results

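The transcriptomes of 2 regulatory T cell populations from human cancer tissue were compared by bulk RNA sequencing. T follicular regulatory (Tfr) cells were sorted by surface protein as lineage-negative CD45+ CD3+ CD4+ cells that carried CXCR5, the chemokine receptor that guides lymphocytes into B cell follicles, and GITR, a receptor abundant on regulatory T cells. Regulatory T (Treg) cells were sorted from the same donors as CXCR5-negative, CD127-negative and CD25-positive CD4+ T cells. Each population was sequenced from 10 donors, which gave 20 libraries and 10 donor pairs. The labels state no question beyond profiling these populations, so the comparison made was Tfr against Treg. Total counts per library ran from 9734537 to 38968142.

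Fewer genes were captured in Treg than in Tfr libraries. With every library thinned to 9734537 counts, 13496 ± 368 genes had a count in Tfr and 12959 ± 515 in Treg libraries (mean ± SD, n = 10 each; adjusted p = 0.0351, two-sided permutation test over 6 quality measures), and the number was higher in Tfr in 9 of 10 donors. Of the 10997 genes tested below, 1.83 ± 0.928% had no count in a Tfr library and 3.39 ± 1.34% in a Treg library (adjusted p = 0.0351). Total counts did not differ by this test (adjusted p = 0.788). In 1 Treg library there were 7873 genes at 1 CPM or more, against 9454 to 11165 in the other Treg libraries, although its 25507092 counts were the most in its group.

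**Figure D1:**
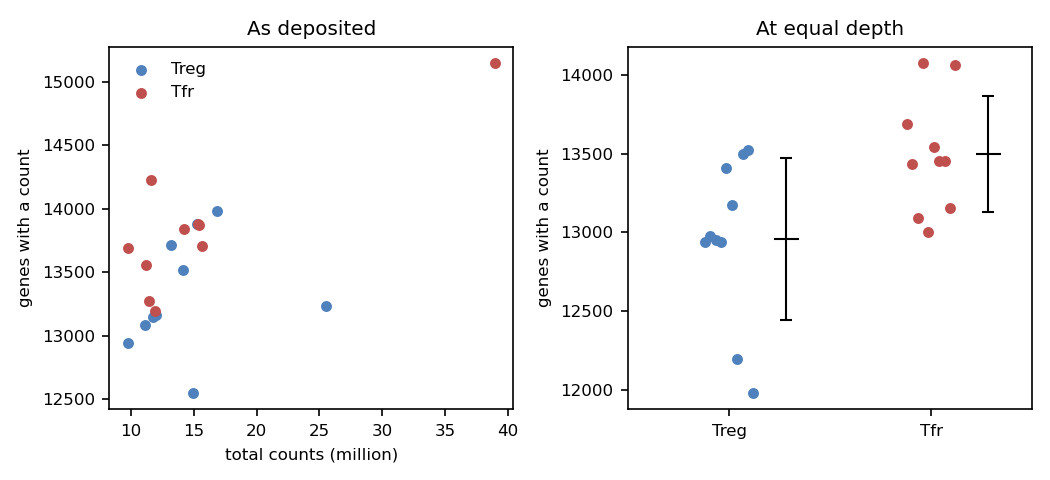
Genes with at least 1 count against total counts for the 20 libraries as deposited (left), and genes with a count after every library was thinned to 9734537 counts (right), Tfr in red and Treg in blue, with the mean ± SD of each group as bars. At equal depth the Tfr libraries held 13496 ± 368 genes and the Treg libraries 12959 ± 515.

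The transcripts of the sorted surface proteins were examined first, as a check of the labels. CXCR5 stood at 90.0 ± 58.5 CPM in Tfr and 7.17 ± 12.6 CPM in Treg libraries (n = 10 each; log2 fold change 3.65 ± 1.13, SE), and was higher in Tfr in 9 of 10 donors. In 1 Tfr library CXCR5 had no count; whether its label or sort is right cannot be told from the files, and it was kept in its group. TNFRSF18, which encodes GITR, was at 418 ± 134 CPM in Tfr and 417 ± 173 CPM in Treg. IL2RA, which encodes CD25, was at 421 ± 272 against 559 ± 267 CPM, and IL7R, which encodes CD127, was at 775 ± 335 against 616 ± 270 CPM. CD4 (1150 ± 327 against 1161 ± 337 CPM), PTPRC, which encodes CD45 (1949 ± 302 against 1949 ± 512 CPM), CD3D, CD3E and CD3G had log2 fold changes between -0.35 and 0.10. None of these 9 genes reached an adjusted p of 0.05 (edgeR quasi-likelihood test), CXCR5 included (adjusted p = 0.915). DESeq2 called CXCR5 (adjusted p = 0.0116), though that fit also called many genes in other groupings of the libraries, as given below. By edgeR the log2 fold change of CXCR5 was 4.47 without 1 donor. With the donor block it was 5.4 ± 1.45 (SE), at an edgeR adjusted p of 0.645.

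The gene with the smallest p between the populations was TCF7, the transcription factor TCF-1 that maintains memory-like and follicular T cells. It stood at 145 ± 94.5 CPM in Tfr and 15.3 ± 11.7 CPM in Treg libraries, a log2 fold change of 3.25 ± 0.59 (SE), and was higher in Tfr in all 10 donors. SH2D1A, the adaptor SAP that follicular T cells need to stay in contact with B cells, was at 359 ± 76.5 against 189 ± 76.3 CPM (log2 fold change 0.92 ± 0.23), also higher in all 10 donors. GZMK, a granzyme, was at 97.7 ± 136 against 5.27 ± 8.14 CPM (log2 fold change 4.21 ± 1.23, and 4.95 without 1 donor) and higher in Tfr in all 10 donors. Its medians were 35.1 and 2.21 CPM, and its Tfr level was uneven. In donors 9 and 10 both libraries were near 0, at 0.58 against 0 and 0.80 against 0.56 CPM, so their direction carries little weight. IL10RA, a chain of the interleukin-10 receptor, was at 290 ± 85.6 against 492 ± 148 CPM (log2 fold change -0.76 ± 0.20) and lower in Tfr in 9 of 10 donors. None of them passed the threshold over all genes: the edgeR quasi-likelihood test called 0 of 10997 genes at an adjusted p of 0.05, with the smallest adjusted p at 0.158 for TCF7 and at 0.137 with the donor as a block. At an unadjusted p under 0.05 there were 475 genes, 200 higher and 275 lower in Tfr, where 550 would arise by chance. With the donor block there were 548, and the balance turned, with 338 higher and 210 lower. DESeq2, which tested 15227 genes, called 260, of which 57 were among the genes tested by edgeR, and with the donor block it called 841, of which 570 were. All 4 genes above were among the 260, at DESeq2 adjusted p of 3.12e-07 for TCF7, 0.00487 for SH2D1A, 0.00584 for GZMK and 0.0213 for IL10RA. These values are read with caution, since other random splits of the libraries gave a median of 174 and up to 248 DESeq2 calls. In the simulation, which held only the genes tested by edgeR, 46 of 155 DESeq2 calls were false. In simulated libraries with the spread of these data, the same edgeR test found 94% of genes changed 16-fold and 38% of those changed 4-fold, but 6.3% of those changed 2-fold, among genes with a mean of at least 50 CPM.

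**Figure D2:**
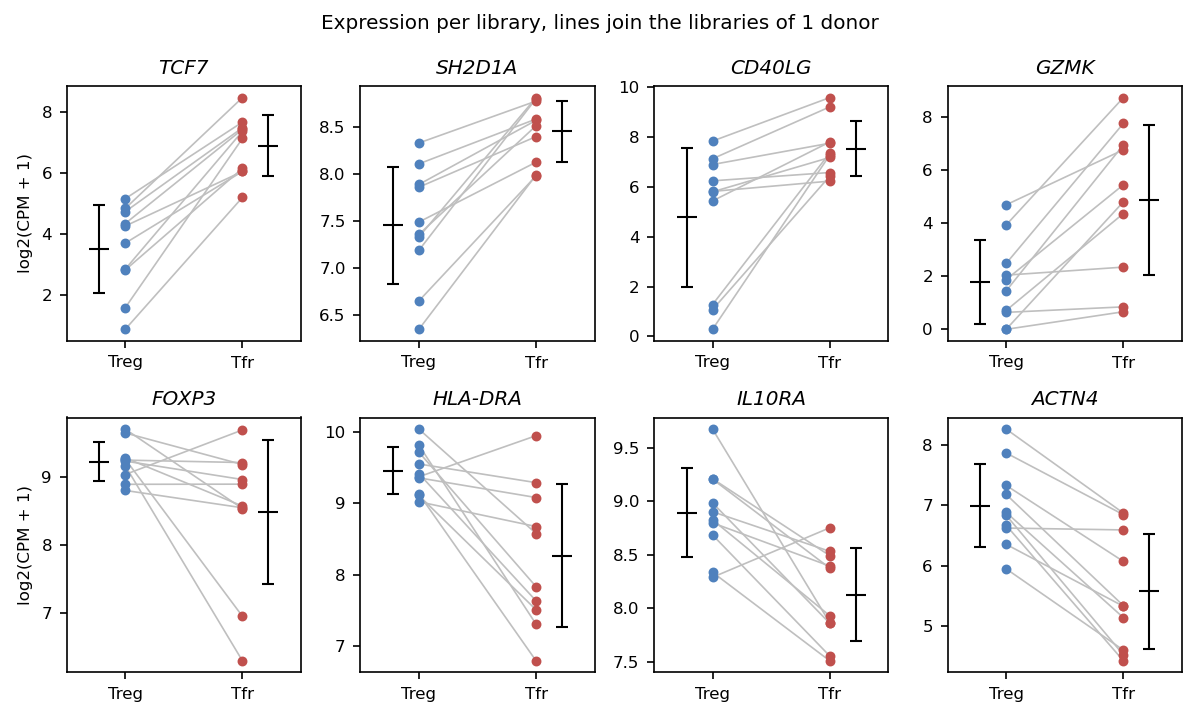
Expression of 8 genes as log2(CPM + 1) in each library, Treg in blue and Tfr in red, with grey lines joining the libraries of a donor and black bars for the mean ± SD (n = 10). TCF7, SH2D1A, CD40LG and GZMK were higher in Tfr in all 10 donors, ACTN4 was lower in all 10, HLA-DRA and IL10RA were lower in 9 and FOXP3 in 8. The GZMK values of donors 9 and 10 were near 0 in both populations.

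Genes of the follicular T cell programme were higher in Tfr as a group. The Tfr sort, as described above, used GITR and not CD25 or CD127, so other CXCR5+ T cells within it cannot be told apart from Tfr cells. Of 27 measured members 22 had a positive and 5 a negative log2 fold change, with a median of 0.81, and 11 were higher in Tfr in at least 8 of 10 donors while 0 were lower in as many. The summed CPM of the list was 6235 ± 2401 in Tfr and 5069 ± 2097 in Treg, higher in Tfr in 6 of 10 donors. Besides SH2D1A, the kinase gene PASK was at 133 ± 60.3 against 37.8 ± 34.6 CPM. CD40LG, the ligand with which helper T cells stimulate B cells, was at 250 ± 233 against 71.2 ± 72.3 CPM and higher in all 10 donors. The master regulator BCL6 was at 154 ± 133 against 49.5 ± 35.9 CPM and higher in Tfr in 8 of 10 donors, but was not called (adjusted p = 0.9997, and 0.301 with DESeq2). The Tfr libraries of highest BCL6, from donors 8 and 3 (480.9 and 248.7 CPM), were also those of lowest FOXP3 (77.5 and 122.6 CPM) and highest CD40LG. BCL6 was picked out after its values were seen, as were the following members. PDCD1, which encodes PD-1, was at 138 ± 111 against 141 ± 119 CPM, ICOS at 681 ± 264 against 649 ± 324 CPM, and the B cell attractant CXCL13 at 723 ± 627 in Tfr against 1447 ± 1853 CPM in Treg. CXCL13 was higher in Tfr in 5 of 10 donors, and its log2 fold change was negative here, 0.40 with the donor block and 0.87 with log2(TPM + 1). The list passed limma's camera test with a preset correlation (adjusted p = 1.27e-05 over 23 lists; 1.55e-06 with the donor block), and adjusted p = 0.233 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 1 did, SH2D1A.

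Naive and central memory T cell genes (11 of 19 higher, median log2 fold change 0.12, adjusted p = 0.134 by camera) held TCF7, which passed when adjusted over the list alone, while NOSIP, another member, was at 47.2 ± 18.2 in Tfr against 89.6 ± 49.5 CPM. Co-inhibitory receptors (10 of 15 higher, median 0.35, adjusted p = 0.108) included KLRB1, which encodes CD161, at 326 ± 176 against 170 ± 85.4 CPM, and BTLA, an inhibitory receptor that binds HVEM, at 212 ± 123 against 121 ± 61.2 CPM. With the share of undetected genes as a covariate the naive list passed, higher in Tfr (adjusted p = 0.00172). It did not with the covariate and an estimated correlation (adjusted p = 0.141).

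**Figure D3:**
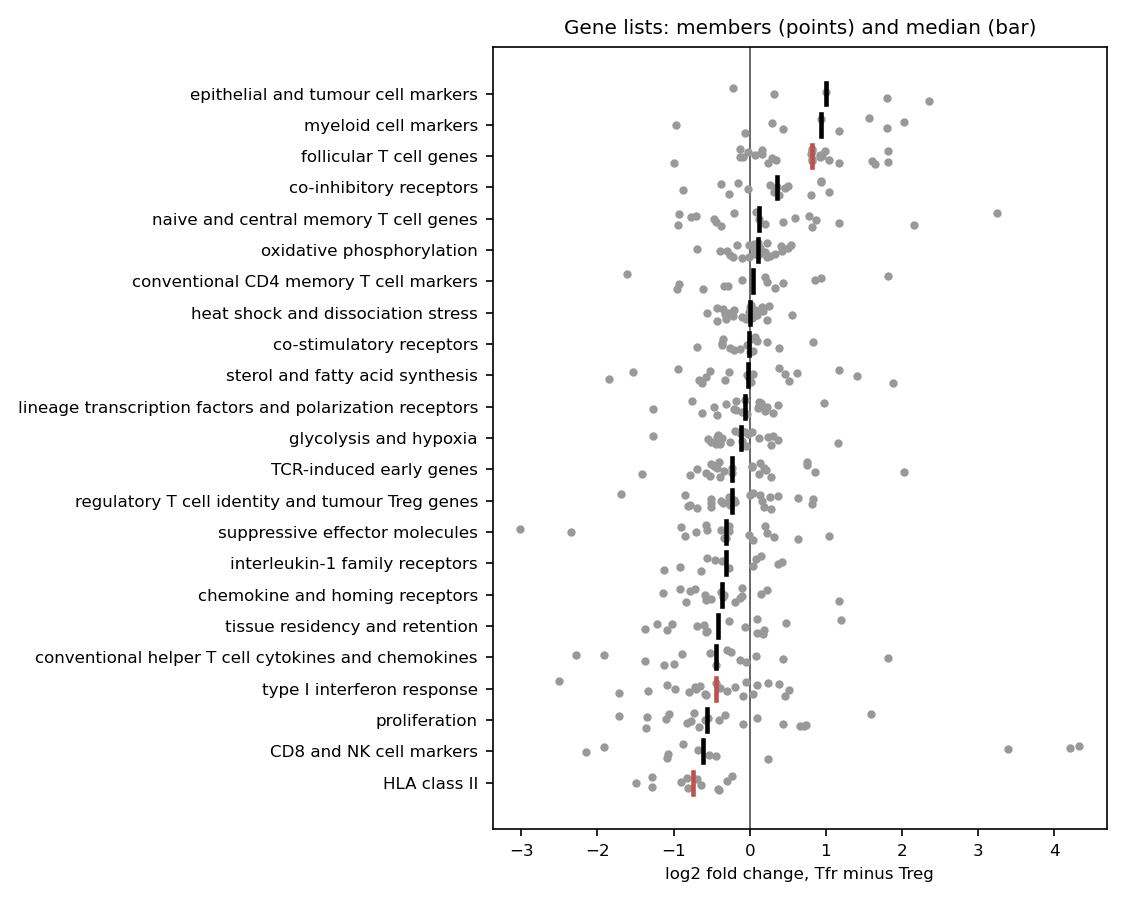
Log2 fold change (Tfr minus Treg) of each measured member, as points, and the median, as a bar, for the 23 lists tested, with red bars for the 3 lists past an adjusted p of 0.05 by camera with a preset correlation. The medians of those lists were 0.81 for follicular T cell genes, -0.44 for the type I interferon response and -0.75 for HLA class II.

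Genes of Treg identity and tumour Treg cells did not pass as a list, with or without the donor block. Of 26 such genes, 10 had positive and 16 negative log2 fold changes (median -0.24). Camera gave an adjusted p of 0.332, and 0.172 with the donor block. FOXP3, the lineage-defining transcription factor, was at 429 ± 221 CPM in Tfr and 609 ± 125 CPM in Treg (log2 fold change -0.51 ± 0.29), CTLA4 at 694 ± 542 against 901 ± 583 CPM, TNFRSF9, which encodes 4-1BB, at 254 ± 130 against 305 ± 182 CPM and the tumour Treg chemokine receptor CCR8 at 162 ± 86.5 against 279 ± 279 CPM. These 4 were chosen after their values were seen. MAGEH1 was at 397 ± 119 against 226 ± 145 CPM and the phosphatase gene DUSP4 at 390 ± 170 against 556 ± 154 CPM. Suppressive effector molecules (6 of 19 higher, median -0.31) gave an adjusted p of 0.367. They passed, lower in Tfr, with the donor block (adjusted p = 0.0477) and with the share of undetected genes as a covariate (0.00596). Neither call held with an estimated correlation (adjusted p = 0.224 and 0.141). Among them GZMB, which encodes granzyme B, was at 35.2 ± 47.7 in Tfr against 284 ± 573 CPM in Treg, with medians of 10.6 and 49.2 CPM. Its log2 fold change was -3.01, but -2.03 without 1 donor and -1.63 with DESeq2. FGL2, a secreted inhibitor of T cell responses, was at 7.16 ± 9.22 against 36.6 ± 32.3 CPM. Co-stimulatory receptors (8 of 16 higher, median -0.02, adjusted p = 0.751) included TNFRSF1B at 823 ± 292 against 1046 ± 268 CPM and CD27 at 331 ± 80.8 against 254 ± 128 CPM. The TCR-induced early genes (11 of 24 higher, median -0.24, adjusted p = 0.751) included PHLDA1 at 229 ± 73.4 against 394 ± 285 CPM. No member of these 4 lists passed over all genes or adjusted over the list alone, except MAGEH1 in the latter with the donor block.

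HLA class II genes were lower in Tfr as a group. All 12 members had a negative log2 fold change, with a median of -0.75, and 5 were lower in Tfr in at least 8 of 10 donors. The summed class II CPM was 4481 ± 2531 in Tfr and 6594 ± 3907 in Treg libraries, lower in Tfr in 9 of 10 donors (permutation p = 0.0848, and p = 0.0449 by exact sign flips within donors, both two-sided on log2 CPM). HLA-DRA, the alpha chain of HLA-DR, was at 382 ± 273 against 717 ± 170 CPM (log2 fold change -0.91 ± 0.32), and HLA-DMA, which loads peptides onto class II molecules, at 98.0 ± 55.7 against 239 ± 200 CPM (log2 fold change -1.28 ± 0.49). The list passed camera (adjusted p = 1.51e-07; 1.76e-05 with the donor block), and adjusted p = 0.233 with an estimated correlation. No member passed over all genes or adjusted over the list alone, except HLA-DRA in the latter with the donor block. Markers of myeloid cells, which carry class II, had a median log2 fold change of 0.94, with a summed CPM that was higher in Tfr in 5 of 10 donors. HLA-DRB1 and HLA-DRB5 are near-identical, and reads between them are uncertain.

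Genes of the type I interferon response were also lower in Tfr as a group, with 17 of 23 members at a negative log2 fold change and a median of -0.44. USP18, which turns off interferon receptor signalling, was at 5.65 ± 8.56 against 32.0 ± 30.1 CPM, and XAF1, an interferon-induced apoptosis factor, at 67.1 ± 32.3 against 111 ± 42.5 CPM. The list passed camera with an adjusted p of 0.0353 (0.00143 with the donor block), and adjusted p = 0.438 with an estimated correlation. No member passed over all genes or adjusted over the list alone. When the donors were left out in turn, the call held in 5 of 10 runs, and without the Tfr library that had no CXCR5 count the adjusted p was 0.0557.

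Genes of migration, residency and polarization did not pass as lists without the donor block or a covariate. Tissue residency genes (6 of 16 higher, median -0.42, adjusted p = 0.140) included CXCR6, a receptor of tissue-resident T cells, at 301 ± 99.1 against 450 ± 131 CPM, and RUNX3, a transcription factor of residency, at 45.2 ± 25.6 against 105 ± 65.2 CPM. Chemokine and homing receptors (3 of 18 higher, median -0.36, adjusted p = 0.345) included SELPLG, the selectin ligand PSGL-1, at 614 ± 275 against 920 ± 295 CPM. Lineage transcription factors and polarization receptors (9 of 21 higher, median -0.06, adjusted p = 0.830) held IL10RA, the member that passed when adjusted over the list alone, and TGFBR3 at 39.3 ± 35.2 against 94.9 ± 130 CPM. Cytokines and chemokines of conventional helper T cells (3 of 15 higher, median -0.44) gave an adjusted p of 0.751, and 0.0273 towards lower values in Tfr with the donor block (adjusted p = 0.248 with the block and an estimated correlation). CCL3 was at 9.74 ± 11.1 against 47.4 ± 73.9 CPM, while CD40LG, also a member, went the other way. Interleukin-1 family receptors (5 of 12 higher, median -0.32, adjusted p = 0.865) included the decoy receptor IL1R2 at 165 ± 82.2 against 127 ± 77.1 CPM and IRAK4 at 63.3 ± 33.9 against 47.2 ± 26.9 CPM. Conventional CD4 memory markers were split, 7 of 14 higher (median 0.05, mean -0.0018, positive test statistic, adjusted p = 0.992), with KLRB1 above and VIM, which encodes vimentin, at 329 ± 105 against 503 ± 191 CPM. With the share of undetected genes as a covariate, the residency (adjusted p = 0.00596) and helper cytokine lists (0.00383) passed, lower in Tfr. Neither did with an estimated correlation (adjusted p = 0.141 each).

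Metabolic, proliferation and stress genes did not pass as lists with all libraries and no covariate. Oxidative phosphorylation genes (18 of 27 higher, median 0.10, adjusted p = 0.345) included COX7C, a subunit of cytochrome c oxidase, at 418 ± 91.1 against 288 ± 44.4 CPM. It was higher in Tfr in all 10 donors and passed when adjusted over the list alone, though not with the donor block. The log2 fold change of COX7C was 0.54 ± 0.15 (SE) without and 0.52 ± 0.14 with the block. ATP5G3, a subunit of ATP synthase, was at 320 ± 61.7 against 419 ± 131 CPM. This list passed without the Treg library of 7873 genes (adjusted p = 0.0157, and 0.587 with an estimated correlation). Glycolysis and hypoxia genes (7 of 24 higher, median -0.11, adjusted p = 0.534) included the enzymes ENO1 at 1197 ± 197 against 1565 ± 467 CPM and PGK1 at 684 ± 237 against 928 ± 310 CPM, the latter lower in Tfr in all 10 donors. Sterol and fatty acid synthesis genes (9 of 20 higher, median -0.02, adjusted p = 0.751) included ACACA, the acetyl-CoA carboxylase of fatty acid synthesis, at 22.1 ± 20.1 against 6.02 ± 6.44 CPM, and FADS1 at 7.32 ± 17.3 against 2.75 ± 1.36 CPM, the latter higher in 3 of 10 donors. Without 1 donor the log2 fold change of FADS1 went from 1.41 to -0.62. Proliferation genes (6 of 20 higher, median -0.57, mean -0.37) gave an adjusted p of 0.830 with a test statistic of opposite sign, and the replication licensing genes MCM5 and MCM2 were at 92.6 ± 42.1 against 154 ± 114 and 39.5 ± 39.6 against 101 ± 138 CPM. Without 1 donor the log2 fold change of MCM2 went from -1.35 to -0.58. With the share of undetected genes as a covariate the proliferation list passed, higher in Tfr by the test (adjusted p = 0.00650, and 0.431 with an estimated correlation). The sterol list also had a negative median beside a positive test statistic. Heat shock and dissociation genes (12 of 24 higher, adjusted p = 0.992) had a mean of -0.06 beside a positive test statistic, and included FOS at 4699 ± 1904 against 3198 ± 1743 CPM and JUN at 396 ± 185 against 505 ± 226 CPM.

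Markers of other cell types were measured beside the sorted populations. The summed CPM of 24 myeloid markers was 227 ± 359 in Tfr and 105 ± 35.7 in Treg (7 of 9 tested members higher, adjusted p = 0.865), with TYROBP at 10.6 ± 16.3 against 3.56 ± 1.26 CPM and S100A8 at 8.85 ± 20.8 against 2.17 ± 2.07 CPM. Without 1 donor the log2 fold change of S100A8 went from 2.02 to 0.11, and the lowest for TYROBP was 0.64, from 1.57. Epithelial markers summed to 105 ± 102 against 78.6 ± 96.1 CPM (4 of 5 tested members higher; adjusted p = 0.218, and 0.0477 with the donor block). With the block and an estimated correlation the adjusted p was 0.223. The adhesion molecule CDH1 was at 9.68 ± 12.3 against 1.89 ± 4.41 CPM and KRT8 at 5.41 ± 7.45 against 1.54 ± 2.2 CPM. Without 1 donor their log2 fold changes of 2.36 and 1.80 reached 4.07 and 2.65. CD8 and NK cell markers summed to 546 ± 300 against 699 ± 579 CPM (4 of 12 higher, median -0.61, mean 0.28, negative test statistic, adjusted p = 0.751). Adjusted over the list alone 4 of them passed: GZMK, CD8B at 24.6 ± 40.1 against 2.34 ± 1.37 CPM and FCGR3A at 15.5 ± 32.0 against 0.762 ± 0.827 CPM were higher in Tfr, and GNLY, which encodes granulysin, was lower at 6.34 ± 4.11 against 28.2 ± 34.5 CPM. Without 1 donor the log2 fold changes went from 3.39 to 2.48 for CD8B, from 4.32 to 2.95 for FCGR3A and from -2.15 to -1.51 for GNLY. FCGR3A and GNLY were chosen after their values were seen. With the donor block GZMK alone passed; CD8B was higher in Tfr in 6 and FCGR3A in 4 of 10 donors. The list passed, lower in Tfr, with the share of undetected genes as a covariate (adjusted p = 0.0130, and 0.141 with an estimated correlation). DESeq2 called CD8B (adjusted p = 0.00374) and GNLY (0.0489, and 0.257 with the donor block), as it did COX7C (0.00708) above and IGLL5 (0.0462) and ACTA2 (0.0115) below. The caution on DESeq2 calls given above holds for these genes too. The remaining 4 lists had too few members past the expression filter for a test. Of 4 B cell genes 3 were higher, CD79A at 48.5 ± 37.2 against 14.6 ± 19.0 CPM and MS4A1, which encodes CD20, at 4.44 ± 11.4 against 0.884 ± 0.682 CPM. The MS4A1 difference rested on 1 Tfr library, its log2 fold change of 2.31 being -0.14 without 1 donor and -0.11 with DESeq2. Of 3 plasma cell genes 3 were higher, among them XBP1 at 136 ± 89.2 against 105 ± 71.0 CPM and IGLL5, which passed when adjusted over the list alone but not with the donor block, at 8.20 ± 10.2 against 1.41 ± 1.69 CPM. IGLL5 shares sequence with the immunoglobulin lambda locus and its counts are uncertain. Of 3 stromal and endothelial genes ACTA2, which encodes smooth muscle actin, was lower in Tfr when adjusted over the list alone, at 19.9 ± 14.5 against 91.7 ± 76.8 CPM, and ENG was at 17.9 ± 26.9 against 8.73 ± 11.8 CPM. Of the erythrocyte and platelet markers 1 passed the filter, PPBP, at 1.51 ± 0.720 against 2.85 ± 2.81 CPM.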

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

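The tests of the FOXP3 and CD40LG relation against transcript loss and against shared donor differences were chosen after the result was seen. Within each group, a value was singled out where the gap between the highest or lowest library and its neighbour was a large share of the group's range (Dixon's test). Of 194 groups of values tested 25 stood out, where chance singles out about 1 in 20, or 10.

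Among the Tfr libraries, 1 stood above the others in total counts (gap 0.798 of the range) and 1 in genes detected (0.473). The lowest Tfr library stood apart for CXCR5 (0.722), BCL6 (0.656), TNFRSF18 (0.486), CD3G (0.469), DUSP4 (0.548), CCL3 (0.489), HLA-DMA (0.705), PPBP (0.698), TLN1 (0.475) and LINC00539 (0.580), on the scale of log2 CPM. The highest Tfr library stood apart for FADS1 (0.597), MS4A1 (0.569), S100A8 (0.540) and IL16 (0.490). Among the Treg libraries, 1 stood above the others in total counts (0.549) and 1 below them in genes at 1 CPM or more (0.480). The highest Treg library stood apart for FOS (0.574), CDH1 (0.612) and RPS12 (0.479), and the lowest for XBP1 (0.619), CD8B (0.628), SESN1 (0.494) and CD79B (0.712). BCL6, TLN1, IL16, LINC00539, SESN1, RPS12 and CD79B were chosen after their values were seen.

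FOXP3 and CD40LG were opposed across the 10 Tfr libraries (Pearson r = -0.838, permutation p = 0.00844, adjusted p = 0.0578 over 11 relations, which did not pass; Spearman rho = -0.552, p = 0.105), but without the 2 libraries farthest from the median r was -0.214, so the relation rests on those. The libraries of lowest FOXP3 were at 77.5 and 122.6 CPM, and the lowest Treg library at 445.1 CPM, so no Treg library was as low. This argues against a donor difference in FOXP3 that shows in both sorted populations. The Treg sort used CD25 and CD127 and the Tfr sort did not, so a donor difference hidden by the Treg sort cannot be told from these values. The donors of those libraries had the highest CD40LG in both populations (761.7 and 587.7 CPM in Tfr, 226.7 and 138.2 CPM in Treg; over all donors rho = 0.491, p = 0.153), so a shared difference in CD40LG stays open. T cells without a regulatory programme in the Tfr sort may account for it, and the other regulatory genes followed FOXP3 with r = 0.830 but with a rho of 0.249 (p = 0.492) and r = -0.181 without the 2 libraries, which leaves this open. A loss of transcripts would give a negative rho between FOXP3 and the share of undetected genes. The rho was 0.273 (permutation p = 0.449), of the opposite sign but too uncertain to decide, so this also stays open. A difference in regulatory state within the sorted Tfr cells was not tested.

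DESeq2 called 260 genes where edgeR called 0. Of those calls 58.9% had no count in at least 5 of 20 libraries, against 22.8% of the 15227 genes it tested (Fisher's exact test, p = 2.04e-36). Genes captured in only some libraries would give such a share. In the simulated data 46 of 155 DESeq2 calls were false. The simulation held only the 10997 genes tested by edgeR, and 57 of the 260 calls were among them, so it cannot speak for the others. Depth is argued against, since 222 genes were called after thinning every library to one depth, 210 of them among the 260. Of 24 splits of the libraries into groups of 10, 1 (the real one) gave as many calls, the highest other giving 248 and the median 174. With the donor block, 1 of 24 swaps within donors, the real one, gave as many as 841, the highest other giving 677 and the median 406, so that the real groups gave most calls, with many also from other groupings.

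HLA class II genes were lower in Tfr by the list test, but not with an estimated correlation (adjusted p = 0.233) nor as summed CPM (permutation p = 0.0848), although within donors the sum was lower in Tfr in 9 of 10 (p = 0.0449 by exact sign flips). More genes went undetected in Treg than in Tfr libraries (3.39 against 1.83%). A plain loss of transcripts would thus lower class II in Treg, the opposite of what was seen, which argues against it as the whole cause. With this share as a covariate the median was -0.57, 11 of 12 members staying lower. That fit alone cannot decide, since the share differed between the groups. Antigen-presenting cells in the Treg sort may contribute: their markers were not higher there (log2 ratio Treg over Tfr -0.48, permutation p = 0.215, and p = 0.398 by sign flips within donors), yet class II and the markers were high together across the Treg libraries (rho = 0.782, p = 0.0102, adjusted p = 0.112 over 11 relations), so this stays open although the sort removes lineage-positive cells. A lower class II level in Tfr cells themselves also stays open. The Tfr libraries of lowest FOXP3, from donors 8 and 3, also had the lowest HLA-DRA (110.4 and 157.8 CPM) and CD74 (874.3 and 1523 CPM). HLA-DMA did not follow, at 51.8 CPM in donor 8 and at 182.3 CPM, the highest in Tfr, in donor 3. These values were picked out after they were seen. Whether T cells without a regulatory programme in the Tfr sort account for the lower class II was not tested.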

How the results depend on the processing

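The filter at a mean of 50 CPM, voom without sample weights, the covariate, the omitted single libraries and DESeq2 on thinned counts or on genes counted in at least 15 libraries were chosen after seeing the data. The count of 0 genes by edgeR stayed at 0 with RLE or upper-quartile normalization, no filter, a filter of 5 CPM, the mean of 50 CPM, the covariate, without the Treg library of fewest genes and without the Tfr library with no CXCR5 count. DESeq2 called 260 genes (189 higher, 71 lower, 251 at least 2-fold), 99 with genes counted in at least 15 libraries (73, 26 and 94) and 222 on thinned counts (163, 59 and 215). Limma-trend on log2(TPM + 1) called 3 genes, all higher and at least 2-fold, as did the same without a filter (3) and voom without sample weights (3), while log2(TPM + 0.1) called 2 and voom with sample weights 1. Leaving out each donor in turn gave 0 to 1 genes (0 to 1 higher, 0 to 0 lower, 0 to 1 at least 2-fold), the 1 being TCF7 without 1 donor (adjusted p = 0.0473). The cause was not tested. With a real count of 0 all 100 random splits give as many by construction, which tests nothing; the highest other gave 1.

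With the donor as a block, edgeR called 0 genes, 1 at a mean of 50 CPM (TCF7, adjusted p = 0.0421, higher and at least 2-fold) and 0 with TPM, and DESeq2 called 841 (681 higher, 160 lower, 795 at least 2-fold). The block raised the lists past the threshold from 3 to 6, and to 0 with an estimated correlation. With the block 13 of 100 swaps within donors gave at least 6 (highest other 10), so chance cannot be excluded. By sign flips within donors, genes detected (adjusted p = 0.0147), genes at 1 CPM (0.0492) and the share of the 100 most abundant genes (0.0147) passed, and total counts did not. The summed class II CPM had p = 0.0449 by sign flips, chosen after seeing the data, and 0.0848 by unpaired permutation. With the block the log2 fold changes of CD4 (0.0083), PTPRC (0.025), FADS1 (-0.29) and CXCL13 (0.40) changed sign, and so did the tests of proliferation (adjusted p = 0.493, and 0.684 with an estimated correlation), sterol synthesis (0.928 and 0.930) and heat shock genes (0.183 and 0.609). Adjusted over the list alone, the block added HLA-DRA, FKBP5 and MAGEH1 and lost COX7C, IGLL5, CD8B, GNLY and FCGR3A.

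Without the block, 3 lists passed with the preset correlation, 0 with an estimated one, 3 with TPM, 9 with the covariate, 4 without the Treg library of fewest genes, 2 without the Tfr library with no CXCR5 count (interferon, adjusted p = 0.0557) and 2 to 4 without each donor. The covariate added suppressive effector (0.00596), helper cytokine (0.00383), residency (0.00596) and CD8 and NK genes (0.0130), lower in Tfr, and naive (0.00172) and proliferation genes (0.00650), higher by the test. With the covariate and an estimated correlation 0 lists passed (lowest adjusted p = 0.141), and without either library 0 as well (lowest 0.230 and 0.197). Of 100 random splits 39 gave at least 3 lists (highest other 11), and of 100 swaps within donors 9 did (highest other 3), so chance cannot be excluded for the number of lists.

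DESeq2 turned the log2 fold changes of TNFRSF18 (-0.0077), FADS1 (-0.52) and MS4A1 (-0.11), RLE that of TNFRSF18 (-0.012), and TPM those of PTPRC (0.0033) and CXCL13 (0.87). Leaving out each donor gave -0.055 to 0.13 for TNFRSF18, -0.041 to 0.032 for CD4, -0.013 to 0.20 for CD3D, -0.035 to 0.074 for PTPRC, -0.62 to 1.72 for FADS1, -0.14 to 2.68 for MS4A1, -0.35 to 0.34 for PDCD1 and -0.017 to 0.18 for ICOS. The list tests changed sign for proliferation (0.829) and heat shock (0.799) with TPM, for heat shock (0.625), myeloid (0.785) and CD4 memory (0.894) genes with the covariate, and for myeloid genes (0.913) without the Treg library, as adjusted p. Without the Tfr library with no CXCR5 count they did so for proliferation and CD4 memory genes (adjusted p = 0.917 each). Leaving out each donor did so for TCR-induced (0.343 to 0.976), sterol (0.584 to 0.986), heat shock (0.594 to 0.989), CD8 and NK (0.622 to 0.986), myeloid (0.759 to 0.986) and CD4 memory genes (0.766 to 0.989). The cause was not tested.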

Other observations

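The ribosomal and actin sets, the genes named here other than TCF7, and voom without sample weights were chosen after the data were examined, and the count over donors was added then, before its result was seen. Ribosomal protein genes were higher in Tfr as a group: 80 of 83 had a positive log2 fold change, with a median of 0.33, and their summed CPM was 70640 ± 19170 in Tfr against 56010 ± 15120 in Treg libraries (mean ± SD, n = 10 each), higher in 9 of 10 donors. The set gave p = 2.38e-14 by camera with a preset and p = 0.140 with an estimated correlation, and p = 0.0102 with an estimated correlation and the donor block. The share of the 100 most abundant genes was also higher in Tfr in 9 of 10 donors, and fewer genes were undetected there (1.83 against 3.39%). Whether library quality bears on the ribosomal set was not tested. A set of actin cytoskeleton genes with some others, such as VIM and S100A10, was lower in Tfr, 23 of 28 with a median of -0.25. Camera gave this set p = 3.83e-09 with a preset and p = 0.00957 with an estimated correlation, although its summed CPM was lower in 5 of 10 donors. Both sets were picked after their values were seen and the p-values are unadjusted, so they describe the sets and are no independent support. The median log2 fold change of all tested genes was -0.11 with TMM, -0.11 with RLE and 0.01 with upper-quartile normalization, under which the medians of these sets were 0.33, 0.33 and 0.46 for ribosomal and -0.25, -0.26 and -0.12 for actin genes. Among actin-binding proteins, ACTN4 was at 56.9 ± 38.1 against 141 ± 74.9 CPM and ZYX, which encodes zyxin of focal adhesions, at 150 ± 49.6 against 245 ± 65.5 CPM, both lower in all 10 donors. SESN1, a stress-induced inhibitor of mTORC1 signalling, was at 446 ± 506 against 160 ± 112 CPM and higher in all 10 donors.

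Of 4089 genes with a mean of at least 50 CPM, 26 differed in the same direction in all 10 donors, 17 higher and 9 lower in Tfr, where 7.99 would by chance. Of the 512 ways of swapping the labels within donors 2 gave as many, the real one included, the highest other giving 28 and the median 8, which argues against chance for this count. Over all 10983 genes the count was 54, and 5 of 512 swaps gave as many. Without the donor of the Treg library of fewest genes, 44 of the 4089 genes did so in all 9 donors left, and 2 of 256 swaps gave as many. Limma-trend on TPM called C1orf228 (38.1 ± 27.4 against 2.19 ± 3.75 CPM), LINC00539 (15.3 ± 6.87 against 1.76 ± 3.94 CPM) and TCF7, and voom without sample weights called C1orf228, LINC00539 and MKRN2 (79.6 ± 48.4 against 10.9 ± 16.2 CPM). With the donor block limma-trend on TPM called 0 genes. By edgeR with the block the log2 fold changes were 6.40 for C1orf228, 7.05 for LINC00539 and 5.90 for MKRN2. None of these passed (edgeR adjusted p = 0.481, 0.338 and 0.562). Without 1 donor the log2 fold changes by edgeR went from 4.12 to 4.93 for C1orf228, from 3.11 to 4.62 for LINC00539 and from 2.86 to 3.49 for MKRN2. LINC00539 and other overlapping genes are uncertain, since the reads carry no strand.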
